A study of Homo sapiens with 4 samples.

How the data were processed

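MCF10A cells under standard culture were profiled by ChIP-seq. Cells were crosslinked with formaldehyde, chromatin was sonicated, and libraries were made with the NEBNext Ultra II DNA kit, per the labels' protocols. The series has 4 samples: 53BP1, Pol II S5p, Pol II S2p and an input, each with 1 library. The input was not analysed here. Groups were taken from the sample labels.

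The values used were lists of enriched regions that the authors deposited, 1 per ChIP. The genome build was hg19 and base calls were converted with bcl2fastq 2.20.0.422, per the submitters' processing notes. The aligner, the peak caller, its settings and its control are not given in the sources used here. Peak names within each deposited list carry a single library name. A call on pooled reads could also carry a single name, so the names do not settle whether reads were pooled. Each region has a fold enrichment, which is the authors' ratio over background. It also has a −log10 p-value and a −log10 q-value as deposited, and the lowest −log10 q-value was 1.32 for 53BP1. The deposited score equalled 10 times the −log10 q-value within 1 in 100% of rows. The offset of the summit from the region's start was also used as deposited. Because the values come from 1 library each, with unknown read depth, folds, p-values and q-values rank regions within a list, and between lists only ranks were related. A more deeply sequenced library can give more and wider regions, so the numbers and widths of regions do not compare the factors. If the same input served every ChIP, its noise is shared by the lists, and the lists alone do not show how much overlap that adds.

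The lists held 11605, 62532 and 54601 rows for 53BP1, S5p and S2p. Regions on chromosomes 1 to 22 and X were kept, which left out 1, 2 and 1 rows on other sequences. No list had duplicate or overlapping rows. Positions are given 1-based in hg19. The gene table at hand was of GRCh38, and its last gene on chromosome 1 ends before the last region of the lists, at 249219667, so no gene was named and no position was converted. The planned analyses of promoters and gene bodies, of 21 fixed gene lists, of sequence motifs and of S5p against S2p along genes were therefore not run, and the p53-family question of the title was not addressed at the level of genes.

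Lists were compared by overlap of at least 1 bp. Chance was taken from 1000 random placements of the first list's regions, with chromosome and length kept. Shares have exact Clopper-Pearson 95% intervals, and medians have bootstrap intervals from 1000 draws over regions. Intervals of rank correlations and of matched differences came from 200 bootstrap draws of 1 Mb windows. Each Pol II list was ranked by fold and divided into 5 equal parts (quintiles), and for matching into 50. Summits were compared with 100 random positions per region. The regions named are the 10 of largest fold in each list and the 10 windows of 1 Mb with the most 53BP1 regions, the rule set for the case of no matching annotation. That rule, the overlap tests, the quintiles, the overlap classes and their alternatives were fixed before the data were examined; summit distances, rank correlations and the comparisons by chromosome were chosen afterwards.

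The overlap test was tested on simulated data for 53BP1 and S5p. With 0%, 25% or 75% of 11604 regions planted on S5p regions, in 10 runs each with 100 placements, the largest error was 0.845, 0.405 and 0.232 percentage points. The runs with p under 0.05 numbered 0, 10 and 10. Unplanted regions were placed in the same way as the test's own random placements. The 0% runs therefore do not show how the test behaves when regions of both lists cluster.

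Alternatives were a −log10 q-value limit of 5, the upper 50% of each list by fold, lists of equal length, other overlap definitions, all sequences, rows as deposited, a circular shift, ranking by −log10 q-value and 250 bp windows around summits. Placement that avoids stretches of 1 Mb or more without regions, shifts of 5 to 50 kb and removal of the strongest 1% were added after seeing the data. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.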

Results

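Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out in MCF10A cells, a non-tumour human breast epithelial line, under normal growth conditions. The 3 ChIPs analysed targeted 53BP1, a chromatin protein of the DNA damage response that also binds p53, and RNA polymerase II (Pol II) phosphorylated on serine 5 (S5p) or on serine 2 (S2p) of its C-terminal repeats. S5p marks Pol II near the start of transcription, and S2p marks elongating Pol II. Each ChIP had 1 library, so no difference could be set against a spread between replicates. The title of the series places 53BP1 in p53-family transcription. The lists bear on where 53BP1 lay relative to both forms of Pol II. All intervals are 95% intervals. Those of shares cover counting error with regions taken as independent, and the others come from resampling regions or 1 Mb windows. None covers a spread between replicates.

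Region numbers and widths depend on read depth, which was unknown, so they do not compare the 3 factors. 53BP1 had 11604 regions covering 7.57 Mb, with a median width of 561 bp (quartiles 377 and 794). Pol II S5p had 62530 regions covering 131 Mb, with a median width of 970.0 bp (quartiles 561 and 1966). Pol II S2p had 54600 regions covering 158 Mb, with a median width of 1098 bp (quartiles 621 and 2645). The widest region was 12009 bp in the 53BP1 list, 125529 bp in the S5p list and 161391 bp in the S2p list. The authors' fold enrichment was used only to rank or describe regions within a list, and the median 53BP1 fold was 6.02. At a stricter limit of 5 on the −log10 q-value, the Pol II lists shrank to 35829 S5p and 29833 S2p regions, with median widths of 1579 and 2212 bp.

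Almost every 53BP1 region lay on a Pol II S5p region. The overlap was 11321 of 11604 regions (97.6%, interval 97.3 to 97.8), against a mean of 7.23% and a maximum of 8.09% for 53BP1 regions placed at random on the same chromosomes. Pol II S2p regions met 9152 of the 53BP1 regions (78.9%, 78.1 to 79.6), against 8.16% at random. The random share does not allow for S5p. In the quintile of S5p regions with the highest fold, 9567 of 12506 met S2p, with or without 53BP1. The excess over random therefore need not be a link of 53BP1 to S2p apart from S5p. Of all 53BP1 bases, 98.2% were inside S5p regions and 79.6% inside S2p regions. Each overlap exceeded all 1000 random placements (one-sided permutation p = 0.001, the smallest these placements can give). Pol II regions cluster. Shifting each 53BP1 region by only 5 to 50 kb left chance overlaps of 25.2% with S5p and 28.1% with S2p. The excess thus fell from 13.5 to 3.87 times chance for S5p. For S2p it fell from 9.67 to 2.81 times (6.18 times with placement that avoids stretches without regions). Some Pol II regions were wider than the smallest shifts, so a shifted region could stay on its own Pol II region. That raises the shifted shares, which therefore do not measure clustering alone. With each Pol II list shortened to its strongest 11604 regions, the S2p share was 48.7%, or 10.2 times chance, and the S5p share 91.2%, or 28.8 times chance.

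**Figure D1:**
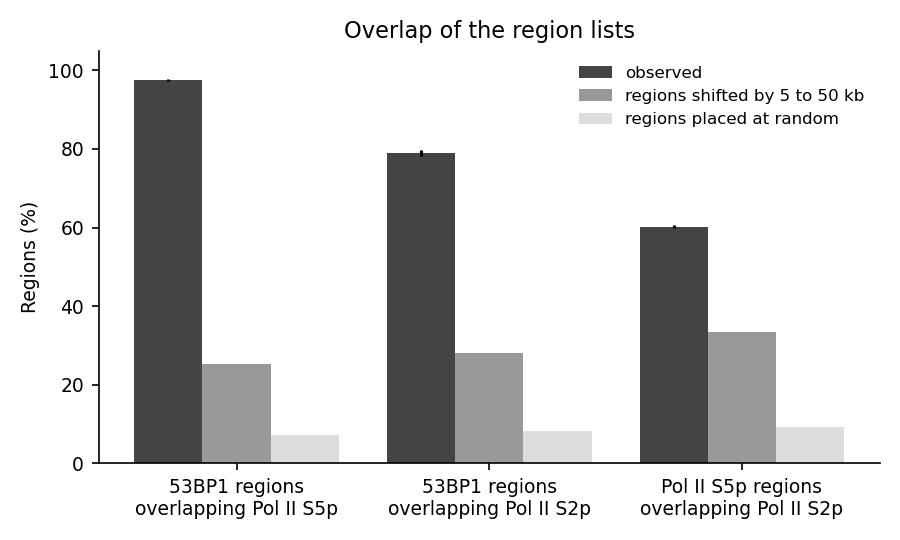
Share of regions (%) in the first list that overlapped a region of the second by at least 1 bp, for 3 pairs of lists. Dark bars are observed shares with exact 95% intervals, mid-grey bars the mean after shifts of 5 to 50 kb and light bars the mean of 1000 random placements; 53BP1 over Pol II S5p had the highest observed share, 97.6%.

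Among Pol II regions, 53BP1 was concentrated on the strongest S5p regions. In the quintile of the S5p list with the highest fold, 8933 of 12506 regions held 53BP1 (71.4%, 70.6 to 72.2). The next lower quintile held it in 3.71% (3.39 to 4.06), and the others in 0.144 to 0.536%. Seen from 53BP1, 10731 of its 11604 regions (92.5%, 92.0 to 93.0) lay on that strongest quintile of S5p. In the strongest of 50 equal bins the share was 99.8%, or 1249 of 1251 S5p regions.

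The relation to S2p strength was shallower. From the weakest to the strongest quintile of the S2p list, 53BP1 was present in 2.86%, 4.42%, 7.88%, 17.7% and 36.8% (35.9 to 37.7) of regions. The strongest S2p quintile took up 5448 of the 53BP1 regions (46.9%, 46.0 to 47.9). The strongest of 50 S2p bins stood apart from the others, with 53BP1 in 74.9% (72.2 to 77.5) of its regions. Strong regions were also wide: median width rose from 579 bp in the weakest to 2483 bp in the strongest S5p quintile, and from 637 to 6125 bp for S2p. Limiting 53BP1 to the upper 50% of its list by fold lowered the share in the strongest S5p quintile to 42.6%, in the next to 0.504% and in the others to at most 0.0320%. Under that limit the S2p shares, from the weakest quintile up to the next to strongest, were 1.13%, 1.95%, 4.12% and 10.6%. Ranking S2p regions by −log10 q-value gave 1.66% and 2.77% in its weakest quintiles.

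**Figure D2:**
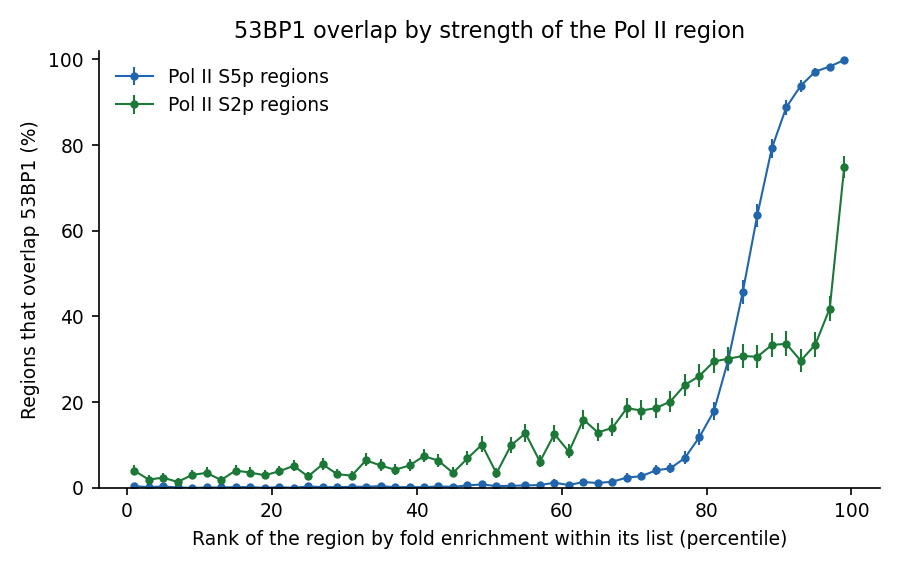
Share of Pol II regions (%) that overlapped a 53BP1 region, by percentile of the Pol II region's fold enrichment within its own list, in 50 equal bins. Points are S5p (blue) and S2p (green) bins with exact 95% intervals; the highest bin reached 99.8% for S5p and 74.9% for S2p.

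The 53BP1 list divided unevenly between the forms of Pol II. Regions on both S5p and S2p numbered 9115 (78.6%) and had the highest median 53BP1 fold, 6.42 (bootstrap interval over regions 6.36 to 6.48), and a median width of 624 bp. Regions on S5p alone numbered 2206 (19.0%), with a median fold of 5.04 (4.92 to 5.13) and a width of 399 bp. Only 37 regions (0.319%) lay on S2p alone, with a median fold of 3.95 (3.72 to 4.15), and 246 (2.12%) lay on neither, with a median fold of 4.14 (3.98 to 4.20). From the Pol II side, 53BP1 was found in 1796 of the 24860 S5p regions without S2p (7.22%, 6.91 to 7.55), against 0.674% at random. It was found in 7711 of the 37670 S5p regions with S2p (20.5%, 20.1 to 20.9). These contrasts were not matched on S5p strength: in the strongest S5p quintile, the median S5p fold was 29.3 with S2p and 12.8 without. At equal S5p fold in that quintile, the 53BP1 share was not higher with S2p (difference -1.16 percentage points, -3.14 to 0.856). Of the 24598 S2p regions without S5p, 6 held 53BP1 (0.0244%, 0.00895 to 0.0531), against 0.794% at random. Since 97.6% of 53BP1 regions lay on S5p, a share below random was largely given in advance. Of the 37 53BP1 regions on S2p alone, 31 lay on S2p regions that met S5p elsewhere. Regions are not independent replicates, so these intervals describe the lists and do not test a condition.

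The S5p and S2p lists overlapped in more than 50% of the regions of each. Of the S5p regions, 37670 (60.2%, 59.9 to 60.6) met an S2p region, against 9.09% at random (one-sided permutation p = 0.001, the smallest possible). Of the S2p regions, 30002 (54.9%, 54.5 to 55.4) met an S5p region, against 9.27% at random. The lists shared 91.0 Mb, which was 69.3% of S5p bases and 57.7% of S2p bases. S5p regions that met S2p had a median width of 1386 bp, against 679 bp for those that did not. After shifts of 5 to 50 kb the chance share of S5p regions on S2p was 33.3%, and the excess fell from 6.63 to 1.81 times chance. Here too, a shifted region could stay on the same S2p region.

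Where a 53BP1 summit lay in both an S5p and an S2p region, it was more often nearer to the S5p summit, in comparisons chosen after the lists had been examined. Of 8724 such summits, 5492 (63.0%, 61.9 to 64.0) were nearer to the S5p summit, with median distances of 71 bp to S5p (68 to 75) and 175 bp to S2p (167 to 185). Where both regions spanned 5 kb or more, 1610 of 2767 (58.2%, 56.3 to 60.03) were nearer to S5p, with medians of 501 bp (367 to 649) and 2623 bp (2320.0 to 2880.2). Taken over all pairs with each mark, the sets of 53BP1 regions differed between S5p and S2p. In the 4112 pairs whose S5p region spanned 5 kb or more, the median distance from the 53BP1 summit to the S5p summit was 179.5 bp (157 to 210.0), against 3800.1 bp for random positions in the same regions. In 3293 pairs with an S2p region of 5 kb or more it was 2357 bp (2123 to 2619), against 3696 bp. Over regions of any width the medians were 78 bp to the S5p summit (random 778 bp, 11250 pairs) and 177 bp to the S2p summit (random 591 bp, 8772 pairs). The 53BP1 summit was within 500 bp of the S5p summit in 58.3% of the wide regions (random 9.01%) and of the S2p summit in 31.8% (random 8.04%). As a baseline, S5p summits were placed in S2p regions of 5 kb or more, with or without 53BP1. Their median distance to the S2p summit was 2972 bp (random 3077 bp, 15833 pairs), and 21.1% were within 500 bp (random 9.25%). 53BP1 summits thus lay nearer to S2p summits than S5p summits in general did. Across regions, 53BP1 fold rank followed S5p fold rank with a Spearman rho of 0.418 (0.394 to 0.436, 11321 regions) and S2p fold rank with a rho of 0.0659 (0.0425 to 0.0884, 9152 regions). In the 9115 regions on both, the direction for S2p turned at equal S5p rank (rho -0.156, -0.177 to -0.136), while the rho with S5p at equal S2p rank was 0.399 (0.383 to 0.419).

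**Figure D3:**
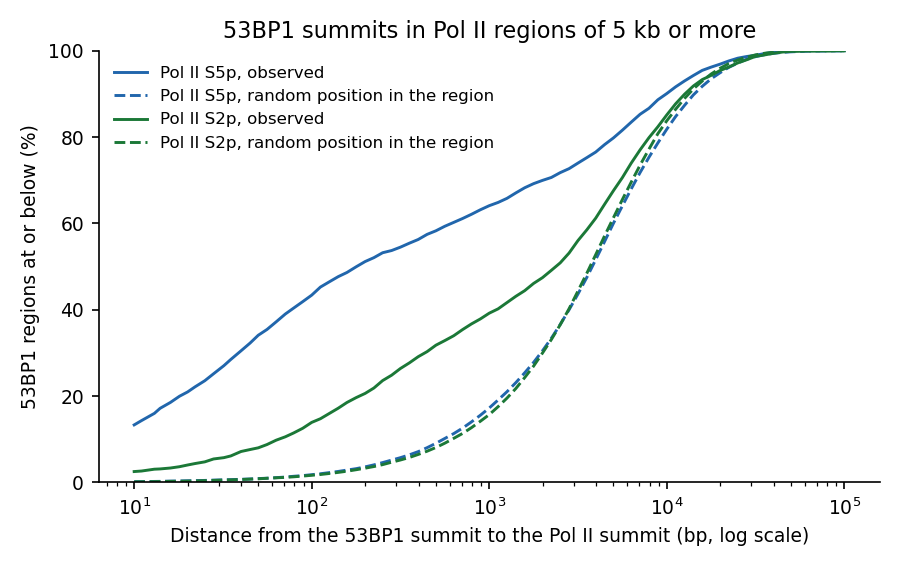
Cumulative share of 53BP1 regions (%) by distance from the 53BP1 summit to the Pol II summit (bp, log scale), in Pol II regions of 5 kb or more. Solid lines are observed and dashed lines random positions in the same regions; medians were 179.5 bp for S5p and 2357 bp for S2p.

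The strongest 53BP1 regions, by the authors' fold, were spread over 5 chromosomes (hg19). The strongest was on chromosome 1 at 149222457 to 149224941, with a fold of 115, followed on the same chromosome by 147735356 to 147736555 (fold 113) and 28974744 to 28976111 (fold 104). Chromosome 17 at 8076161 to 8077207 had a fold of 89.9, and chromosome 12 at 120728873 to 120731365 a fold of 82.6. On chromosome 15, 2 of the 10 lay near each other, at 65587903 to 65589204 (fold 82.3) and 65596693 to 65598174 (fold 68.6). The others were on chromosome 1 at 210546056 to 210547903 (fold 79.8) and 45195575 to 45197182 (fold 71.1), and on chromosome 2 at 88315316 to 88316584 (fold 77.1). All 10 met an S5p region at or above the 99.4th percentile of the S5p list and an S2p region at or above the 89.3rd percentile of the S2p list. Their S5p regions were 1433 to 2870 bp wide.

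The 10 strongest Pol II regions of each list all held 53BP1. The top S5p region was on chromosome 13 at 52023203 to 52031751, with an S5p fold of 300.1, and the chromosome 12, chromosome 1 and chromosome 15 regions at 120728710, 28973761 and 65587735 were on both the S5p and the 53BP1 lists of 10. The top S2p region, on chromosome 17 at 38611643 to 38658186, was 46544 bp long with an S2p fold of 239.96, and its strongest 53BP1 region had a fold of 21.3. Across the 10 strongest S2p regions, widths ran from 5224 to 46544 bp and the 53BP1 fold from 11.8 to 46.7.

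53BP1 regions were most crowded in a few 1 Mb windows on several chromosomes. Chromosome 17 from 7000001 to 8000000 held 48, with 78 S5p and 72 S2p regions. Chromosome 11 from 65000001 to 66000000 held 44, chromosome 16 from 1 to 1000000 held 42, and chromosome 19 from 1000001 to 2000000 and chromosome 1 from 153000001 to 154000000 held 41 each. The other 5 of the 10 windows with the most 53BP1 regions held 39 or 40, and all 10 windows together held 3.56% of the 53BP1 list. Of the 1 Mb windows, 2457 held a region of any list and 2078 held 53BP1. The median window with a region held 3 (quartiles 1 and 6). Across windows, the number of 53BP1 regions followed the number of S5p regions of the strongest quintile (rho 0.923) and the number of all S2p regions (rho 0.840). These rhos do not compare the marks, since only the S5p regions were limited to the strongest quintile.

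**Figure D4:**
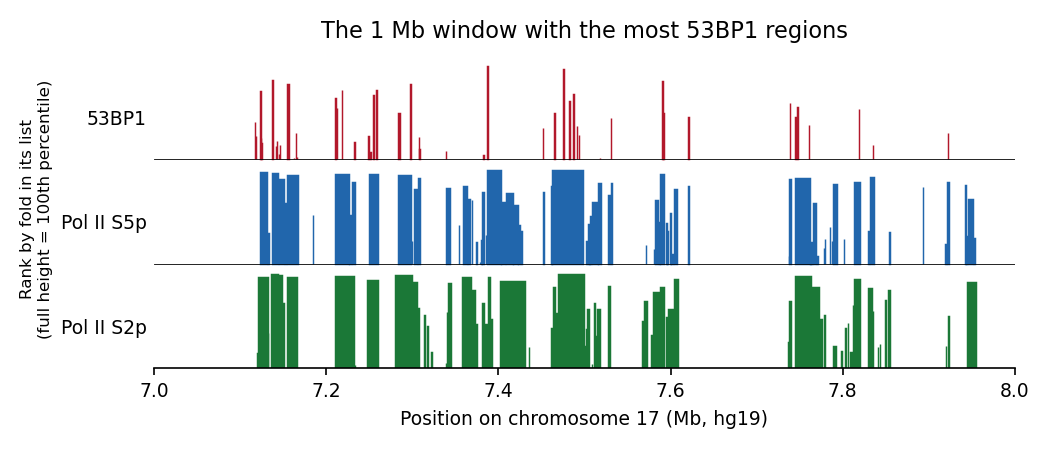
Regions of the 3 lists in the window with the most 53BP1 regions, by position (Mb, hg19). Bar height is the rank of each region by fold within its own list and bar width the region's extent, with the shortest drawn at a minimum line width; the window held 48 53BP1, 78 S5p and 72 S2p regions.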

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

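The shifts of 5 to 50 kb, the placement that avoids stretches without regions and the removal of the strongest 1% were tests added after the main results were seen. All 36 alternatives of the 3 overlap results kept the overlap above chance, at 1.81 to 28.8 times the chance share. The lowest multiples came from the 5 to 50 kb shifts (3.87, 2.81 and 1.81 for 53BP1 on S5p, 53BP1 on S2p and S5p on S2p). Avoiding stretches without regions gave 6.18 for 53BP1 on S2p. Without the strongest 1% the shares were 89.0%, 69.6% and 58.7%, partly by construction, since removing strong Pol II regions removes partners. Keeping rows as deposited removed or added nothing and tested nothing. The share of the strongest S5p quintile with 53BP1 was 69.2% with 250 bp windows around summits and 42.6% with the upper 50% of 53BP1 regions. For the strongest S2p quintile these were 27.8% and 26.3%, and ranking by −log10 q-value gave 39.3%. Fewer 53BP1 regions, or shorter windows, lower such shares by construction; the cause of the change with ranking was not tested. At a −log10 q-value of 5 or more, 53BP1 regions had a median width of 651 bp and fold of 7.17, S5p kept 35829 regions (1579 bp, fold 5.57) and S2p 29833 (2212 bp, fold 4.83), since weak regions were left out. With 50% of the region covered required, 53BP1 regions on S5p alone had a median fold of 5.15. Not run for lack of an hg19 annotation or sequence were the alternatives for promoter and gene shares, gene lists, motifs and S5p against S2p along genes. No paired analysis was possible because each ChIP had 1 library. Unknown depth limits any reading of a Pol II region without 53BP1: it was not detected, not shown to be absent.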

Other observations

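The tests in this part were chosen after the results were seen, except the shift of 53BP1 regions by 5 to 50 kb, the distance of 53BP1 regions outside S5p, the sets matched on S5p fold and width and the comparison of chromosome X at equal S5p fold, which were set after the lists had been examined but before their own values were seen. No biological explanation was tested for any pattern, since the design has no second condition.

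Among the 1251 S5p regions of the strongest of 50 bins, 2 lacked 53BP1: chromosome 1 at 19270248 to 19283805 (S5p fold 62.7) and chromosome 2 at 67624002 to 67626431 (S5p fold 60.03), both singled out after their values were seen. S5p regions with more than 1 53BP1 region numbered 1194 of the 9507 that held any (12.6%), with a maximum of 10. Within the strongest S5p quintile, 53BP1 was present in 52.1% of the narrowest quintile of regions by width and in 74.4%, 76.7%, 75.3% and 78.6% of the wider ones. S5p strength moved with width, from a median fold of 14.2 in the narrowest to 36.3 in the widest, while the number of 53BP1 regions per kb fell from 0.528 to 0.0816. That fall was largely given by construction, since 8313 of the 9507 S5p regions with 53BP1 in the whole list held only 1.

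53BP1 regions lay at the strongest Pol II S5p regions. Chance overlap in Pol II-rich neighbourhoods would have kept the share near the observed 97.6%, but shifts of 5 to 50 kb left a mean of 25.2% and at most 26.4%. Elongating Pol II as a source of signal in any ChIP predicts more 53BP1 where S2p is present, and at equal S5p fold the difference was -1.20 percentage points (-1.40 to -1.03) below the strongest quintile, mostly from the next to strongest (-3.85), with 0.0230 (-0.111 to 0.159) in the weakest. Those quintiles held 574 of the 9507 S5p regions with 53BP1, and within the strongest the difference was -1.16 (-3.14 to 0.856). These comparisons used the presence of S2p and not its strength, and were not matched on width, so they do not exclude this explanation in any quintile. Among 53BP1 regions on both marks, the rho of 53BP1 and S2p fold at equal S5p rank was -0.156 (-0.177 to -0.136). That is opposite to the predicted direction, for detected regions only, and the S2p fold was that of the whole region, not of the 53BP1 summit. Binding of 53BP1, a general pull-down of accessible, Pol II-dense promoters and a stricter detection limit in the 53BP1 library cannot be told apart, because each predicts that 53BP1 fold follows S5p fold among detected regions (rho 0.418), and no unrelated ChIP was analysed here.

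The 10 strongest 53BP1 regions lay in compact Pol II S5p regions, with a median width of 1898 bp. A choice of 10 sharp regions by chance was tested with 10000 sets of S5p regions matched on S5p fold: the middle 95% of their medians ran from 6047 to 20214 bp, and 0% of sets were as narrow. Since the width of these same 10 prompted the test, separate ranks were also compared. Ranks 11 to 20 had a median of 1793 bp, with 0% of sets as narrow. Ranks 21 to 50 had 11048 bp (15.2% of sets as narrow) and ranks 51 to 100 had 10741 bp (51.3%). The strongest 20, 50 and 100 had been examined before, so these ranks are no independent check. Their sets also left out S5p regions of all 100 strongest 53BP1 regions. Regions inflated alike in every ChIP (collapsed repeats, extra copies) cannot be told apart from a feature of these loci: the median S2p fold, 14.8, was lower than in those sets (0% as low), but the sets were wider, and S2p rises with width. In sets matched on S5p fold and width, 97.2% had a median S2p fold at or below it (set median 12.8), yet too few compact regions were as strong, with a median S5p fold of 133 in the sets against 170.2 at the 10.

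In all, 283 53BP1 regions overlapped no Pol II S5p region. Their median distance to the nearest one was 12570.0 bp (8290.0 to 17485), below the lowest of the random placements, 45306 bp. False calls placed evenly at random therefore do not account for the whole group. False calls that favour Pol II-rich neighbourhoods would also lie near S5p, so the distances cannot exclude them. They were weaker, with a −log10 q-value of 5 or more in 25.1% against 73.0% of the others, and S5p signal under that library's own limit may lie beneath some of them, which was not tested.

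Of the strongest S5p quintile, 55.1% (49.8 to 60.4) of regions on chromosome X held 53BP1, against 71.9% on the other chromosomes. At equal S5p fold the difference was -12.8 percentage points (-17.3 to -8.15), so lower S5p fold on X did not account for all of it. The regions were not matched on width or on S2p, and no other cause was tested. Among the 23 chromosomes compared, the next largest differences at equal fold were 6.96 points (3.54 to 10.2) on chromosome 8 and -5.50 points (-9.15 to -1.55) on chromosome 20.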
